A study of Mus musculus with 4 samples.

How the data were processed

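Gene expression was measured in peritoneal macrophages of wild type mice and of mice lacking CD13, the cell-surface aminopeptidase encoded by Anpep, with 2 arrays per group. Per the series text, biotin-labelled cRNA made from total RNA was hybridised to Illumina MouseWG-6 v2.0 BeadChips, on which each transcript is read by beads carrying a gene-specific oligonucleotide. Per the labels, both groups were of the C57BL/6 strain and the cells were peritoneal macrophages; the series text names peritoneal or bone marrow derived macrophages without assigning arrays, and the labels were followed. The number of animals behind each array is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

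The deposited signal table holds the average bead intensity of each probe on a linear scale, without normalization between arrays. Beside each intensity the authors deposited a detection p-value, which falls as the signal of the same array rises and was therefore read as the chance of that signal on background beads. A further deposited table holds intensities that were quantile normalized in GenomeStudio, per the series text. Its sorted values differed from the mean of the 4 sorted signal columns by at most 0.981%, on a linear scale, and its medians lay between 131.5 and 131.6 on the 4 arrays. Whether GenomeStudio subtracted background before the signals were exported is not given in the sources used here, nor is its version.

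The signals were background corrected with the normexp model informed by the detection p-values, offset by 16, quantile normalized and log2 transformed (neqc in limma 3.58.1, R 4.3.3). Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none, and 34807 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID, which supplied current symbols. The deposited files name no genome build. That table was used only for names, for the chromosome and order of genes, and for their distance from Anpep. Probes with a detection p-value under 0.01 on at least 2 of the 4 arrays were kept, which left 14881, of which 2097 had no single symbol. Where a gene had several kept probes, the probe with the highest mean log2 value stood for it, giving 10335 genes or unnamed probes, 8238 of them named.

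Knockout was compared with wild type by lmFit and eBayes in limma, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Errors are the moderated standard error (SE) with 2 arrays per group. For a single value, 2 arrays against 2 cannot give a two-sided exact permutation p below 0.333. A gene not above background on any array of a group has only a bound there. Its fold was computed from the mean of the brighter group against, per array of the dimmer group, the higher of its own value and the lowest value of any detected probe. The number of arrays limits the precision of every value.

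Before the data were examined, 24 gene lists and 11 cell type marker lists were fixed, with a set of sex-linked genes given as values. Lists with at least 3 measured members were tested with camera in limma (preset inter-gene correlation 0.01, two-sided), adjusted within the gene lists and within the cell type lists. The rule for named genes was fixed at the same time. It took Anpep, then up to 12 genes per direction with the largest change among those that passed with no overlap of the groups. Places left went to genes with the smallest unadjusted p among those changed at least 1.5-fold without overlap, which are given as values that did not pass. Unnamed probes and unnamed gene models took no place. It also took up to 4 passing members of each list or, where none passed, the 2 with the smallest unadjusted p, all measured sex-linked genes, and the genes within 10 Mb of Anpep that passed. A gene outside this rule is said to have been chosen after its values were seen.

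The pipeline was tested on simulated data. In 20 simulations on 10335 genes with the fitted spread, 200 genes were changed by known amounts in knockout against wild type. Of genes changed by 1 log2 unit, 7.03% passed. The share was 84.6% for 2 log2 units and 98.5% for 4 log2 units, with a mean of 7.35 unchanged genes called. These shares hold for 200 changed genes. With fewer changed genes the adjustment requires a smaller p, so the shares may be lower for the measured arrays, where 5 genes passed upward and 5 downward. Among simulated lists of 20 independent genes shifted by 0.4, camera with the preset correlation called 100% and called 1% of unshifted lists, while camera with an estimated correlation called 0% of the shifted lists. Members of a real list can vary together, which these simulations do not cover, so the 1% need not hold for the real lists.

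Alternatives covered the background correction, the normalization, the authors' normalized values, the filter on dim probes, the treatment of several probes, the variance model, the replicate number as a block, the threshold, the set test and the omission of each array. Median scaling on detected probes and the omission of the chromosome that carries Anpep were chosen after seeing the data. Chromosomal neighbourhood was examined with Fisher's exact test on genes with an unadjusted p under 0.01, a comparison added after the changed genes were seen.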

Results

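Transcript levels were compared between peritoneal macrophages of CD13 null and wild type mice, with 2 arrays in each group, to find genes whose expression differs when CD13 is absent. The median non-normalized intensity was 167.1 and 127.6 on wild type arrays 1 and 2, and 122.4 and 109.0 on knockout arrays 1 and 2. The number of probes above background was 14799 and 14823 in wild type and 14740 and 13659 in knockout. After normalization, Pearson's r across genes, which are not independent replicates, was 0.981 between the wild type arrays, 0.979 between the knockout arrays and 0.967 to 0.977 between arrays of different groups.

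Anpep, which encodes CD13, was 5.33-fold lower in knockout than in wild type macrophages. Its log2 intensity was 13.58 and 13.40 on the wild type arrays and 11.12 and 11.03 on the knockout arrays, a log2 change of -2.41 ± 0.18 (SE) with a limma adjusted p of 0.0265. The array carries 1 probe for Anpep, and it remained above background on both knockout arrays. The position of this probe relative to the deleted part of the gene is not given in the sources used here, so the residual signal cannot be assigned to intact transcript. The adjusted p was above the threshold when any of the 4 arrays was left out (0.124 to 0.171) and without the filter on dim probes (0.0642).

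Of 10335 genes and unnamed probes, 5 were higher and 5 were lower in the knockout at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 965, where 517 would be found with no effect. This excess was gone when wild type array 2 was left out and stayed when any other array was left out. Genes vary together across arrays, so the count alone does not show an effect of genotype. The groups did not overlap for 39.9% of genes, against 33.3% by chance. Among the probes used that were above background in both groups, Ctsc fell the most. It encodes cathepsin C, a lysosomal dipeptidyl peptidase that activates granule serine proteases. Ctsc was 23.2-fold lower in the knockout (log2 change -4.54 ± 0.17, limma adjusted p = 0.00185), and its 3 probes gave log2 changes of -4.33 to -4.54. Trim30a, an interferon-inducible member of the tripartite motif family, was at least 6.87-fold lower (limma adjusted p = 0.0271) and was not above background on either knockout array. Ifi202b, an interferon-inducible gene of the Ifi200 family, was 7.65-fold lower (log2 change -2.93 ± 0.22, limma adjusted p = 0.0265). Another probe of Ifi202b, not above background in the knockout, was at least 12.7-fold lower, and its remaining probe was not above background on any array. BC018473, chosen after its values were seen, was at least 5.50-fold lower (limma adjusted p = 0.0117). Over the other settings the smallest falls were log2 changes of -2.54 for Trim30a and -2.41 for BC018473, so their bounds hold only for the main processing. Trim30a and Ifi202b have close paralogs, and probes of such families can read more than a single gene.

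Lbp, which encodes lipopolysaccharide-binding protein, was at least 5.63-fold higher in the knockout and was not above background in wild type (limma adjusted p = 0.0379). Its log2 change lay between 1.79 and 3.46 over the 17 other settings, so this bound holds only for the main processing. Fah, which encodes the last enzyme of tyrosine breakdown, was 5.14-fold higher (log2 change 2.36 ± 0.19, limma adjusted p = 0.029). The other 3 that passed upward were probes with no symbol in the annotation used here, ILMN_2692986, ILMN_1221102 and ILMN_2692989, chosen after their values were seen. They were at least 14.6-fold, 11.8-fold and 10.9-fold higher, and none was above background on a wild type array. In the same order, their lowest log2 changes over the other settings were 3.40, 2.77 and 2.81, so these bounds too hold only for the main processing. Ctsc and these 3 probes passed in each of the 17 other settings in which they were tested. Lbp, Fah, Trim30a, Ifi202b and BC018473 lost significance when some or all single arrays were left out, and the first 4 of these also without the filter on dim probes, with their direction kept. Lbp was also not called with cyclic loess or without the chromosome of Anpep. With each array scaled to a common median over all probes, the median of all genes was shifted by -0.33 on the log2 scale and the calls, without subtracting that shift, became 15 higher and 194 lower.

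**Figure D1:**
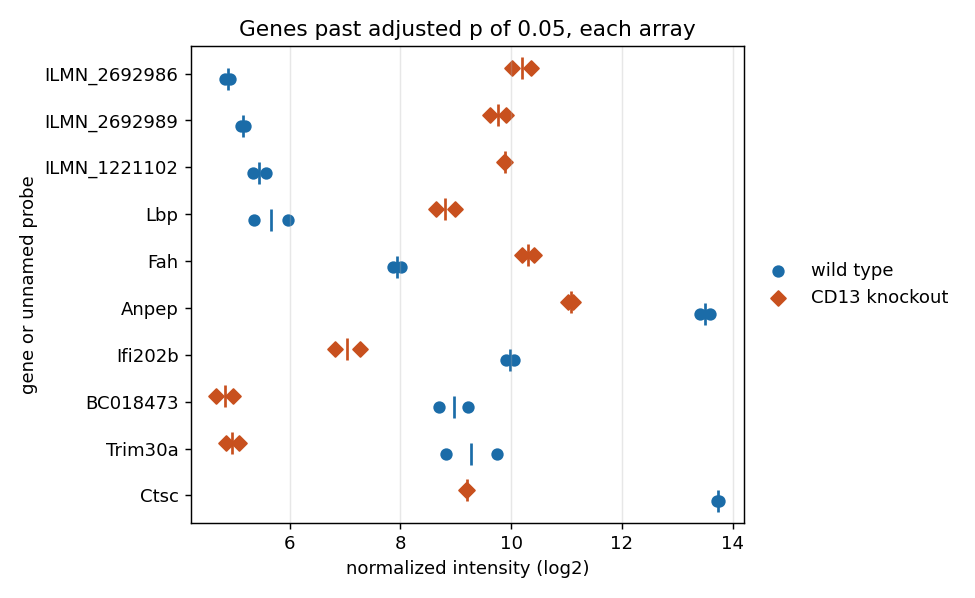
Normalized log2 intensity (x axis) of the 10 genes or unnamed probes past the threshold (y axis) on each of the 4 arrays. Circles are wild type arrays, diamonds are CD13 knockout arrays and vertical ticks are group means; Ctsc lies at a mean of 13.74 in wild type and 9.20 in knockout, and no gene shown has overlapping groups.

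Below the threshold, the next genes with higher values in the knockout were Klra10, a Ly49 family receptor (log2 change 1.46 ± 0.17), Slc6a12 (1.28 ± 0.17), Fam83f (1.44 ± 0.19), Fbxo46 (1.16 ± 0.17), Aoah (1.84 ± 0.30), which encodes an enzyme that deacylates lipopolysaccharide, and Prss46 (1.07 ± 0.18). Kif5c, Dgat2, Cited4 and C5ar2 were not above background in wild type, with values at least 1.27-fold to 2.78-fold higher in the knockout. The limma adjusted p of these 10 genes lay between 0.126 and 0.223. With lower values were Klra22, at least 2.25-fold (limma adjusted p = 0.0586), Zbtb32 (log2 change -1.85 ± 0.19), Itgam (-1.59 ± 0.19), Cdkal1 (-1.33 ± 0.18) and Sema4b (-1.46 ± 0.20). Fam169b, Rras2 and the probe used for Nectin2 were not above background in the knockout, with values at least 3.29-fold, 2.23-fold and 2.17-fold lower. Another detected probe of Nectin2 gave a log2 change of -0.65. Klra10 and Klra22 belong to a family of near-identical genes.

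Of 24 gene lists, 6 shifted as sets, each downward in the knockout, by camera with a preset correlation. None of the 6 calls held with an estimated correlation (adjusted p = 0.632 to 0.653) or by fry (adjusted p = 0.332 to 0.521). With an estimated correlation, camera also called 0% of the simulated lists shifted by 0.4. The loss of the calls under that setting therefore does not show that the lists were unshifted. Of 20 measured interferon-stimulated genes, 17 had a lower mean in the knockout and the median log2 change was -0.42 (camera adjusted p = 5.18e-05). Of these, Trim30a fell over all genes tested, and 3 passed when adjusted over the list alone, namely Oas2, Trim30a and Usp18. Of 20 genes typical of large peritoneal macrophages, the main resident population of the cavity, 17 had a lower mean, with a median of -0.51 (camera adjusted p = 6.34e-05). Tgfb2 (-1.03 ± 0.23) and F5, which encodes coagulation factor V (-1.72 ± 0.42), had its smallest unadjusted p-values. The value of F5 was -2.34 without wild type array 1 and -1.11 without wild type array 2. Of 23 immediate early and heat shock genes, which respond within minutes to handling and stress, 20 had a lower mean, with a median of -0.29 (camera adjusted p = 0.000322), including Hspa1a (-1.22 ± 0.30). Ier2 was not above background in the knockout.

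Of 22 inflammatory cytokines and chemokines, 18 had a lower mean, with a median of -0.38 (camera adjusted p = 0.00151), including Il1b (-0.79 ± 0.20) and Ccl24 (-0.79 ± 0.23). Of 9 genes of eicosanoid synthesis, 7 had a lower mean, with a median of -0.58 (camera adjusted p = 0.013). Alox15, which is also in the large peritoneal macrophage and alternative activation lists and is the only measured eosinophil marker, had a log2 change of -1.39 ± 0.48 (-2.11 without wild type array 1 and -0.67 without wild type array 2) and Ltc4s, which encodes leukotriene C4 synthase, of -0.87 ± 0.28. Of 25 genes of Toll-like receptor signalling, 17 had a lower mean, with a median of -0.18 (camera adjusted p = 0.02), including Nfkbiz (-0.98 ± 0.19) and Tlr2 (-0.55 ± 0.17). No member of the lists other than Trim30a passed over all genes, and outside the interferon list 0 members of these lists passed when adjusted over the list alone.

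Leaving out wild type array 1 ended the calls of the interferon-stimulated (adjusted p = 0.115), cytokine (adjusted p = 0.118) and Toll-like receptor lists, leaving out wild type array 2 those of the large peritoneal macrophage (adjusted p = 0.0862) and eicosanoid lists, and leaving out knockout array 1 those of the Toll-like receptor and eicosanoid lists. The immediate early and heat shock list was called in each of these cases. The median of the large peritoneal macrophage list was -0.96 without wild type array 1 and -0.27 without wild type array 2, that of the eicosanoid list -0.89 and -0.26, and that of the interferon-stimulated list -0.23 and -0.55. The cytokine list had a median of -0.25 without wild type array 1, and the Toll-like receptor list of -0.19 without wild type array 1 and -0.11 without knockout array 1. The median of the eicosanoid list was -0.66 without knockout array 1, so its call was lost there without a smaller shift.

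**Figure D2:**
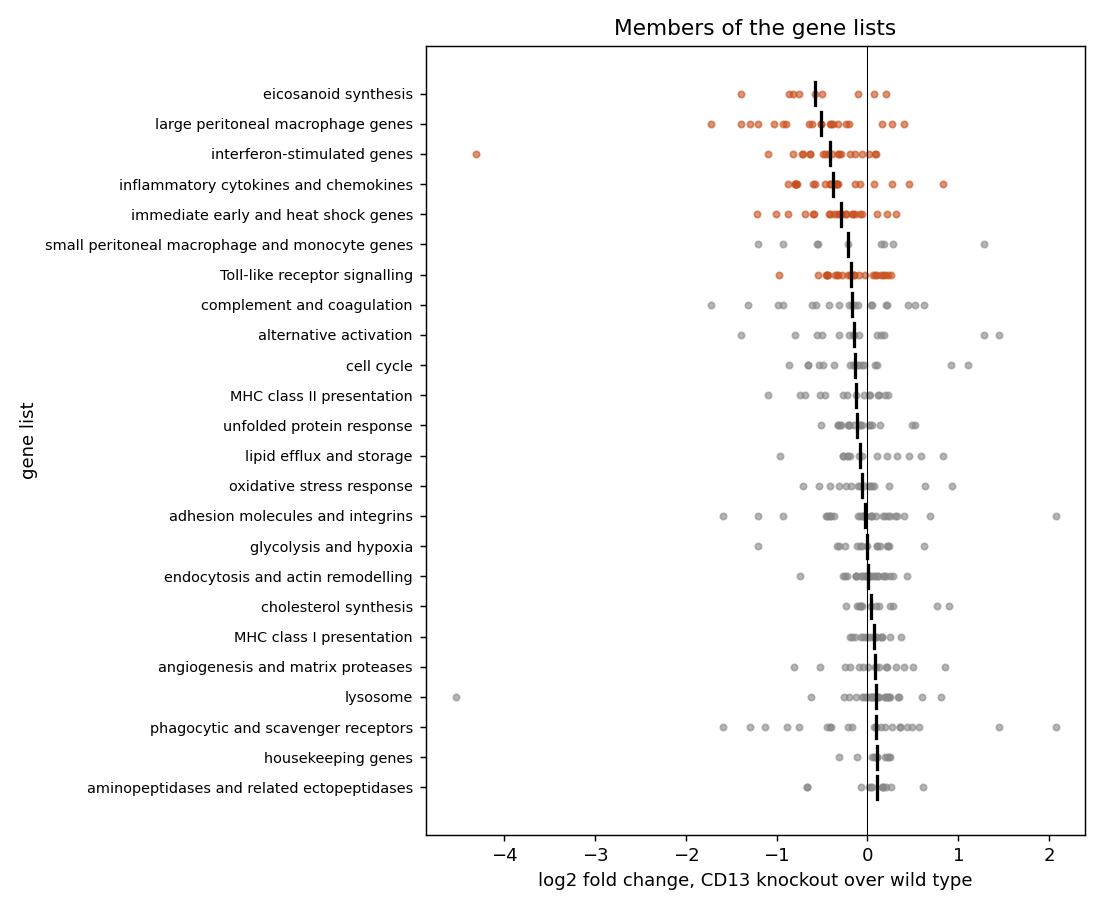
Log2 fold change of knockout over wild type (x axis) for each measured member of the 24 gene lists (y axis), 1 point per gene, with black bars at list medians. Orange marks the 6 lists that passed camera with a preset correlation, whose medians lie between -0.58 and -0.18; other lists are grey.

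The other 18 gene lists were not called. In the lysosome list Ctsc fell, the other 25 members did not pass, and the median of 26 members was 0.09. Itgam and Itgax, which encode the integrin chains CD11b and CD11c, had log2 changes of opposite sign (-1.59 ± 0.19 and 2.07 ± 0.40). The value of Itgax was 1.47 without wild type array 1 and 2.67 without wild type array 2. Both passed when adjusted over the list alone in the phagocytic receptor list (23 measured) and in the adhesion list (28 measured), and neither passed over all genes. H2-Ob of MHC class II presentation (-1.09 ± 0.22), Plac8 (-1.20 ± 0.24) and Chil3 (1.29 ± 0.31) of the small peritoneal macrophage list, and Pmvk of cholesterol synthesis (0.90 ± 0.17) likewise passed over the list alone and not over all genes. In the alternative activation list, of which 0 members passed, Cd163 had a log2 change of 1.45 ± 0.36. Among aminopeptidases and related ectopeptidases, 9 of 12 had a higher mean with a median of 0.11 (camera adjusted p = 0.799), and 0 members passed, with a log2 change of -0.67 ± 0.17 for Dpp4. Complement and coagulation (median -0.17, camera adjusted p = 0.0989) and MHC class II presentation (median -0.13, camera adjusted p = 0.0742) lay nearest to the threshold among lists not called, and both were called downward in some other settings. MHC class I presentation, endocytosis and actin remodelling, cell cycle, lipid efflux and storage, oxidative stress response, unfolded protein response, glycolysis and hypoxia, angiogenesis and matrix proteases, and housekeeping genes had medians between -0.14 and 0.10. The median and the test differed in sign for the phagocytic receptor and glycolysis lists, and the mean and the test for the lysosome, endocytosis, glycolysis and lipid lists and, among the cell type lists, for plasma cells.

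Markers of other cells of the peritoneal cavity gave 6 lists with at least 3 measured members, and camera called 0 of them. It also called 0 with an estimated correlation, but that setting called 0% of the simulated shifted lists and so adds nothing to this result. The medians were 0.43 for T and NK cells (5 measured) and 0.15 for neutrophils (7 measured), both with a camera adjusted p of 0.172. They were -0.32 for B cells (9 measured), 0.05 for plasma cells (3 measured), -0.53 for mast cells and basophils (5 measured) and -0.27 for dendritic cells (6 measured). No marker passed over all genes. Adjusted over the list alone, Cd22 (0.93 ± 0.20) and Ms4a1 (not above background in knockout) passed among B cell genes, Lat (2.05 ± 0.41, with 1.46 without wild type array 1 and 2.63 without wild type array 2) among T and NK cell genes and Ltf (2.00 ± 0.45) among neutrophil genes. Without wild type array 2, and with median scaling, the T and NK cell and neutrophil lists were called upward. Without the chromosome of Anpep, which carries Lat, the camera adjusted p was 0.576 for the T and NK cell list and 0.158 for the neutrophil list. Eosinophil, mesothelial, erythroid and platelet lists had 1 or 2 measured members and the adipocyte list 0, so they were not tested. Alox15, the single measured eosinophil gene, passed over that list alone, where the adjustment covers 1 gene. Xist was detected on all 4 arrays (log2 12.54 to 12.79), and no probe of Eif2s3y, Kdm5d or Uty was above background on any array.

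Genes on the chromosome that carries Anpep were compared with genes of other chromosomes, with gene neighbourhood taken from assembly GRCm38.p6. Of 7 passing genes with a known chromosome, 4 lay on that chromosome, namely Anpep, Ctsc, Trim30a and Fah, with Ctsc and Fah within 10 Mb of Anpep. At an unadjusted p under 0.01, leaving out Anpep, there were 5 of 44 genes (11.4%) within 10 Mb, 31 of 581 (5.34%) on the rest of the chromosome and 163 of 7599 (2.15%) on other chromosomes. The odds ratio against other chromosomes was 5.85 (95% confidence interval 1.78 to 15.1, two-sided Fisher's exact p = 0.00263) within 10 Mb and 2.57 (1.68 to 3.84, two-sided Fisher's exact p = 2.33e-05) on the rest. Over the whole chromosome it was 2.79, and it lay between 1.87 and 3.01 under 6 other scalings and background corrections. Neighbouring genes are not independent, so these intervals are too narrow. Among the genes named above, Zbtb32, Nectin2, Itgam, Itgax, Lat, Cd22, Fam169b, Rras2, Sema4b, Fbxo46, Dgat2 and C5ar2 also lie on this chromosome.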

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

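Median scaling on detected probes and the omission of the chromosome of Anpep were chosen after seeing the data. Of the 10 genes and probes that passed, each kept its direction in every setting in which it was tested. Leaving out an array leaves fewer samples, and the lone array of a group is then assumed to vary like the other group; for other shifts below the cause was not tested.

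Higher and lower genes, 5 and 5, became 7 and 10 without background correction, 5 and 8 with an offset of 50, 15 and 194 with median scaling, 6 and 8 with the authors' values, 3 and 2 without a filter on dim probes (more genes tested), 1 and 3 for probes detected on all 4 arrays, 5 and 9 for every kept probe, 6 and 10 with an intensity trend, 303 and 425 at an unadjusted p with 1.5-fold change, and 3 and 2 without the chromosome of Anpep. Leaving out single arrays gave 3 to 7 higher and 1 to 4 lower. Median scaling moved the share of lower calls from 50% to 92.8%. Anpep had a log2 change of -2.41 without the filter (adjusted p = 0.0642) and of -2.50 to -2.33 without single arrays (adjusted p = 0.124 to 0.171), against a range of 0.000452 to 0.171 over its 17 settings.

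With median scaling the Toll-like receptor list was not called (camera adjusted p = 0.0598, with a median of -0.18 relative to all genes). For every kept probe that list was not called either (camera adjusted p = 0.218), and its median shrank from -0.18 to -0.08. The eicosanoid list was not called without the filter (camera adjusted p = 0.116), where its median shrank from -0.58 to -0.09. MHC class II presentation, not called above, was called downward in 7 settings with all arrays (adjusted p = 0.0022 to 0.0425), the authors' values among them, and without wild type array 2 and knockout array 2. Small peritoneal macrophage genes were called without the filter, cell cycle for probes detected on all 4 arrays and for every kept probe, and complement and coagulation for every kept probe and without the chromosome of Anpep, each downward. The count of 6 gene lists became 0 with an estimated correlation and 0 with fry, and 3 to 7 without single arrays. The cell type lists, 0, became 2 with median scaling, 1 for every kept probe (erythroid cells, downward), and 0 to 2 without single arrays. Under median scaling Psmb9 (-0.11), Vav1 (-0.0654) and Lcn2 (-0.0122) took a negative sign; relative to the shift of -0.33 in all genes under that scaling they stayed higher (0.22, 0.26 and 0.32). Without single arrays Dcn ranged from -1.68 to 0.0639, reversed without wild type array 2, and Sparc from -1.14 to 0.68, reversed without wild type array 2 and without knockout array 2 (0.638); none of these 5 genes passed.

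Same-numbered arrays did not deviate together (correlation across genes -0.024, 2 pairs), so the numbers were not taken as pairs; with the replicate block there were 6 higher and 7 lower genes, and the 10 calls were kept. The slide as a block was not run, since the files used name no slides. Only 30.2% to 32.7% of probes were above background on each array, so dim genes have only bounds.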

Other observations

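Every test in this part was chosen after the results it bears on had been seen, and each explanation below is a hypothesis.

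Genes on the chromosome of Anpep reached an unadjusted p under 0.01 more often than genes elsewhere. A share of 0.035 of 10000 circular shifts along the genome gave at least the observed 36 genes on that chromosome, and the highest number in a shift was 44. Shifts that overlap that chromosome keep part of its own genes, so these counts do not show how often other regions reach them. The shifts were run after changed genes on this chromosome had been seen, so that share does not settle whether their placement is chance. A candidate explanation is DNA of another mouse strain carried along with the targeted allele, although the labels give C57BL/6 for both groups. A segment confined to the surroundings of Anpep predicts more such genes near Anpep than farther away on the same chromosome. That odds ratio was 2.27 (95% confidence interval 0.653 to 6.36). A longer segment need not give such a difference, so the explanation stays open. Variants under single probes are a further candidate and predict that other probes of the same gene do not move. For 11 genes with another detected probe, the median ratio of the other probes' change to that of the probe used was 0.845 (bootstrap 95% interval 0.360 to 1.06). In 10 of the 11 the other probes moved the same way. These values argue against such variants as a general cause in the 11 genes. Such variants stay open for single genes among the 11 and for the 25 genes with a single kept probe. An effect of CD13 loss on the changed genes of this chromosome also stays open, because the arrays do not separate it from their position.

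The 6 lists that were lower in the knockout could rest in part on single arrays. With the array left out that shrank it most, the mean shift kept 0.818 of its size for the cytokine list (bootstrap 95% interval over members 0.305 to 1.18). For the immediate early and heat shock list it kept 0.830 (0.595 to 1.11). Most of the mean shift of these lists thus remained, while the median of the cytokine list went from -0.38 to -0.25 without wild type array 1. The intervals resample genes and not arrays, so they cannot show how far the shifts would vary between arrays. The mean shift kept 0.711 (0.0662 to 0.986) for the Toll-like receptor list and 0.632 (0.143 to 0.851) for the interferon list. It kept 0.488 (0.320 to 0.763) for the eicosanoid list and 0.341 (-0.0173 to 0.541) for the large peritoneal macrophage list. Whether a single array decides the shift stays open for these 4. At least 5 of the 6 lists were called under each of 6 other scalings and background corrections, so most calls did not depend on that choice. This cannot exclude array scaling or background correction as the cause. Camera compares a list with the other genes, so a constant added to an array moves both alike. Several of the other settings also share the quantile normalization. A lower share of macrophages in the knockout preparations cannot be told apart from a change within macrophages: the lowest cell type list mean, that of B cells, lay -1.36 standard errors from 0, and the 6 list means did not differ detectably (Cochran's Q 7.05). A biological effect of CD13 loss stays open, as does any difference in how the cells were collected.

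Some genes at an unadjusted p under 0.01 on other chromosomes are neighbours, among them Klra10 and Klra3, Mndal and Ifi202b, and C4b and C4a, chosen after their values were seen, each pair from a single gene family. Segregating strain differences at other loci could give such runs. With pairs from a single family left out, there were 4 neighbouring pairs of genes at an unadjusted p under 0.01, against a mean of 3.35 over 10000 shuffles, and a share of 0.434 of shuffles gave as many, so these data do not decide it.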
